A study of Mus musculus with 7 samples.

How the data were processed

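BFU-E cells were isolated by depletion of other lineages and sorting for c-kit with low CD71, cultured with SCF, IGF-1 and erythropoietin, and crosslinked after treatment, per the labels' protocols. Chromatin from 10000000 cells per immunoprecipitation was pulled down with a rabbit antibody to GR or to PPARα. Libraries of 200 to 400 bp were selected. Per the submitters' processing notes, adapters were handled with cutadapt and reads aligned with Bowtie, with mm9 as the genome build. Versions of both are not given in the sources used here. Per the file headers, peaks were called with MACS 1.4.2 for each ChIP library against 1 input library. The settings were a p cutoff of 1.00e-05, a model fold of 5 to 30, a band width of 300 bp and an effective genome size of 1.87e+09. The larger library was scaled towards the smaller and 1 read was kept per position. Duplicates made up 14% of 8743774 GR reads, 13% of 2241595 PPARα reads and 12% of 34195484 input reads. No replicates were pooled.

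Each peak has, per the file headers, a position and width in bp, a summit, a count of reads in the peak after duplicate removal, a score equal to 10 times the negative log10 of the caller's p, a fold enrichment over background and an FDR in percent. In the GR table the name of the score column is a spreadsheet error, and its place was used. The scores are capped at 3100, reached by 3 GR and 13 PPARα peaks. The authors also deposited shorter lists, which were found to hold exactly the peaks with a fold ratio of 10 or more (1058 GR and 1623 PPARα) and their summits. Fold and score are the authors' values. Their sizes were compared only within a list, while folds were also correlated across the lists over pairs. The scale of fold and score depends on depth. At the genome-wide background, which is the fragment length times the reads divided by the genome size, 1 read is worth a fold of 5.92 in the GR table and 25.1 in the PPARα table. Within a tolerance of 0.02 reads, 772 GR folds (66.7%) and 1196 PPARα folds (72.4%) were whole numbers of such reads, called whole-read folds below. A background that the input did not raise gives such folds, but a raised one can also give a whole number. A GR peak on chromosome 13 with 195 reads and a fold of 5.89, or 1 such read, was among them. The median fold was 35.5 for GR and 125.5 for PPARα, or 6.00 and 5.00 reads at the genome-wide background. A fold of 10 equals 1.69 reads in the GR and 0.398 reads in the PPARα table.

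Overlap was counted per peak at a minimum of 1 bp on the full tables. Chance placement was estimated from 10000 circular shifts of the PPARα list, each chromosome taken to end at its last peak. Summit distances were set against 10000 random summit positions within the same peaks. Folds of shared and other peaks were set against 10000 random sets from the same list. Quartiles of a list were formed by rank, with ties kept in genome order. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, since reads and neighbouring peaks are not independent. The overlap count was tested on simulated data with the real peak numbers and widths: with 0, 116 and 578 planted overlaps among 1157 GR peaks, 0, 116 and 578 were recovered. Planted peaks were given the same start and the others were placed at random, so this checks the counting only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

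The groups, tests, alternatives and naming rule were fixed before the data were examined. The rule named the 5 peaks of highest fold in each list and the 10 shared peaks with the best mean rank of fold. Alternatives were the fold 10 lists, a fold of 20, an FDR of at most 5%, other definitions of overlap, local moves of peaks and autosomes alone. Lists of receptor target, erythroid, progenitor, hepatocyte, myeloid and megakaryocyte or mast cell genes had been fixed, and so had tests of genomic location and of receptor, GATA and ETS motifs. They were not run, because no genome or annotation of the build of the files was used here and positions were not converted. With 1 library per antibody no test between treatments or antibodies across replicates was made.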

Results

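Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where 2 nuclear receptors contact the genome of mouse burst-forming unit erythroid cells (BFU-E), early progenitors committed to the red cell lineage. The cells came from E14.5 fetal livers of 129/SvImJ mice. The receptors were the glucocorticoid receptor (GR), which binds glucocorticoids such as dexamethasone, and PPARα, a receptor for fatty acids and related ligands that the synthetic agonist GW7647 activates. The series lists 7 samples: each antibody in untreated cells, after dexamethasone, and after dexamethasone with GW7647, plus input DNA. Peak lists of 2 samples are analysed here, GR and PPARα after 4 h with 100 nM dexamethasone and 10 μM GW7647. The other 5 samples were not analysed here, so the effect of either compound on binding was not measured. There was 1 library per antibody, and no value below has a replicate check. The GR library held 7516221 reads after duplicate removal, the PPARα library 1959992 and the shared input 30047397. The GR library was thus 3.83 times as deep as the PPARα library. The header of the PPARα peak table names a ChIP read file marked for dexamethasone alone, without the further mark that its run name, the input and the GR read file carry. The PPARα list may therefore come from reads of cells given dexamethasone without GW7647, and the files do not settle which. The library labelled PPARα with both compounds is called the PPARα library below, and its treatment rests on the sample label.

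The question posed by the pair of libraries is whether GR and PPARα occupy the same places, with both ligands present if the label of the PPARα library holds. A large part of the called peaks coincided. Of the 1157 GR peaks, 751 (64.9%, exact 95% interval 62.1 to 67.7%) overlapped a PPARα peak by at least 1 bp. Of the 1651 PPARα peaks, 765 (46.3%, interval 43.9 to 48.8%) overlapped a GR peak. In 10000 circular shifts of the PPARα list along its chromosomes a mean of 0.189 GR peaks overlapped, and the highest shift gave 9 (one-sided permutation p = 1e-04, the smallest these shifts can give). When each PPARα peak was instead moved at random within 100 kb, which keeps the regional distribution, a mean of 2.20 GR peaks overlapped and the highest draw gave 10. The intervals cover counting error over peaks only. Both lists were called against the same input, so their errors are not independent. Among peaks at least 80 bp wide in both lists, a restriction chosen after the data were seen, the overlapping share of GR peaks was 38.3% (317 of 828). That of PPARα peaks was 48.1% (326 of 678). The restriction took out 329 GR and 973 PPARα peaks. A wide GR peak whose PPARα partner was under 80 bp then counted as unshared.

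Most sites with strong enrichment were found in both lists. In the quartile of GR peaks with the highest fold enrichment, 286 of 289 (99.0%) overlapped a PPARα peak, against 101 of 290 (34.8%) in the lowest quartile. In the PPARα list the corresponding shares were 377 of 413 (91.3%) and 109 of 413 (26.4%). Ranked by reads rather than fold the share was lower, since 140 of the 176 GR peaks with at least 25 reads (79.5%) overlapped a PPARα peak and GR-only peaks reached 180 reads. The median fold enrichment of GR peaks was 41.5 for the 751 shared peaks and 23.7 for the 406 found in the GR list alone. Among PPARα peaks the medians were 175.8 for shared peaks and 100.4 for the 886 found in that list alone. Each difference was larger than in any of 10000 random sets of peaks of the same size drawn from the same list. Peaks of 1 library are not replicates, so this describes the lists and not the spread between experiments.

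**Figure D1:**
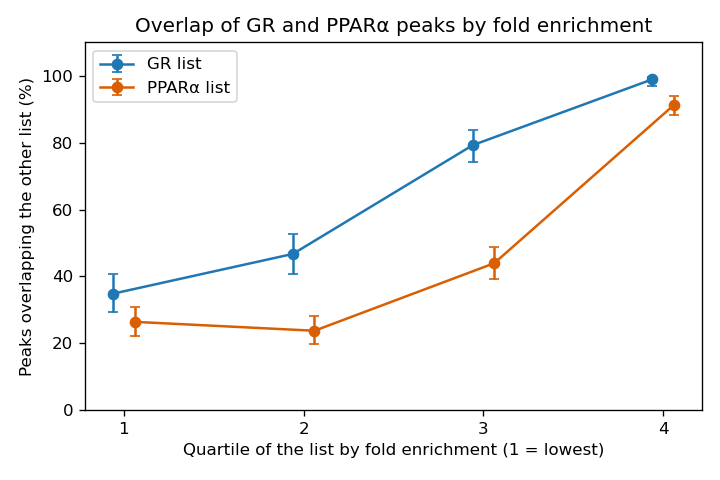
Share of peaks (y axis, %) that overlap a peak of the other list, for the quartiles of each list by fold enrichment (x axis). Points are shares and bars exact 95% binomial intervals. In the highest quartile 99.0% of GR and 91.3% of PPARα peaks were shared, in the lowest 34.8% and 26.4%.

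The leading sites were the same places in both lists. All positions are from the deposited lists, on mm9. The peak with the highest fold in either list lay on chromosome 17 from 16286998 to 16287232 for GR, with a fold of 255.0 and 88 reads. The PPARα peak there ran from 16287055 to 16287168, with a fold of 1381 and 97 reads, and the summits were 2 bp apart. Next came a site on chromosome 9 from 78195308 to 78195442, with GR fold 248.8 and PPARα fold 1080. Each library had 44 reads there and the summits fell on the same base, position 78195348. A further site on chromosome 9, from 96417172 to 96417438, had GR fold 223.6 and PPARα fold 883. On chromosome 1 the GR peak from 81372079 to 81372299 had fold 201.4 and 89 reads, and the PPARα peak there had fold 803 and 101 reads. The fifth GR peak by fold, level with the peak on chromosome 4 given below, lay on chromosome 13 from 23836960 to 23837190 (fold 183.6). The PPARα list had 2 peaks there, with folds of 527.3 and 100.4. In the PPARα list, the third and the fourth lay on chromosome 2 from 155247378 to 155247467 (fold 929) and on chromosome 17 from 81741861 to 81742023 (fold 904). Both were also GR peaks, with GR folds of 162.8 and 177.7. The 10 shared sites with the best mean rank included 4 more. They began in the GR list at 10692112 on chromosome 17, at 58662414 on chromosome 4, at 19249278 on chromosome 10 and at 86525625 on chromosome 14, with GR folds of 154.0 to 183.6 and PPARα folds of 703 to 803. The FDR given by the peak caller for the GR peak on chromosome 1 was 14.3%, and for the leading site on chromosome 17 it was 12.5%. No gene is given for these sites, because the gene table used here is of another assembly (GRCm38).

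The summits of overlapping GR and PPARα peaks nearly coincided. Over 774 overlapping pairs the median distance between summits was 4 bp (quartiles 2 and 10 bp). It was 0 in 78 pairs and at most 5 bp in 472 pairs (61.0%). Many summits lay at the midpoint of their peak. The summit lay within 1 bp of the midpoint for 40.1% of GR and 49.6% of PPARα peaks in these pairs, and both summits lay within 5 bp of it in 272 of the 774 pairs. The midpoints were a median of 8 bp apart. The planned comparison with summits placed at random within the peaks, whose medians averaged 29.99 bp, is therefore no fair chance level. In the 268 pairs with both summits over 5 bp from the midpoint, a subset chosen after the data were seen, the median summit distance was 6 bp and the median midpoint distance 12.75 bp. Both summits lay on the same side of the midpoint in 186 of these pairs (69.4%, exact 95% interval 63.5 to 74.9% over pairs).

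**Figure D2:**
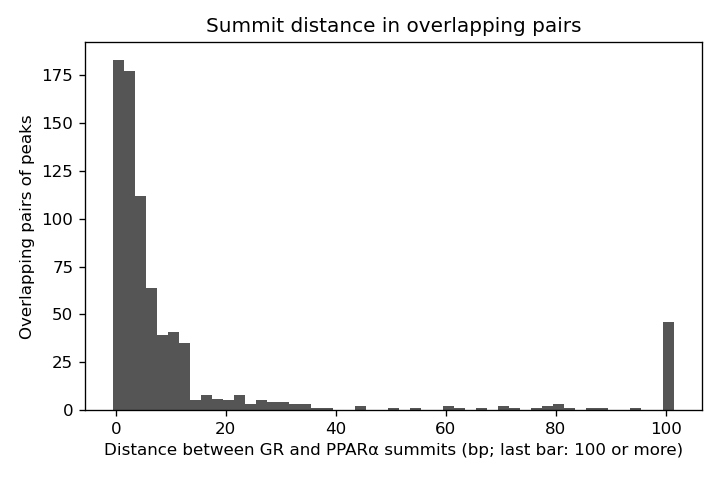
Distance in bp between the GR and the PPARα summit (x axis) in the 774 overlapping pairs of peaks, as a count of pairs (y axis). The median is 4 bp, and distances of 100 bp or more are gathered in the last bar.

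Shared sites held about as many distinct reads in the PPARα library as in the deeper GR library. Among 716 pairs in which 1 GR peak matched 1 PPARα peak, the median ratio of PPARα to GR reads was 0.941 (quartiles 0.714 and 1.14), whereas the ratio of the library depths was 0.261. No PPARα peak holds fewer than 4 reads, so pairs with few GR reads cannot reach the depth ratio. For the 126 pairs with at least 25 GR reads, where this limit does not apply, the median ratio was 0.896 (quartiles 0.640 and 1.03) and 10 pairs had a ratio at or below that of the depths. The peaks of a pair were called separately and differ in width, and only sites called in both lists enter. Across the 716 pairs the folds of both libraries were correlated (Spearman's rho 0.797, Pearson's r of log2 fold 0.898). Both folds are over a background that the same input can raise, which can move them together. The reads in the peaks, which are not divided by a background, gave a rho of 0.788 and an r of log2 reads of 0.878. These are correlations across peaks within 1 pair of libraries, and peaks are not independent replicates.

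**Figure D3:**
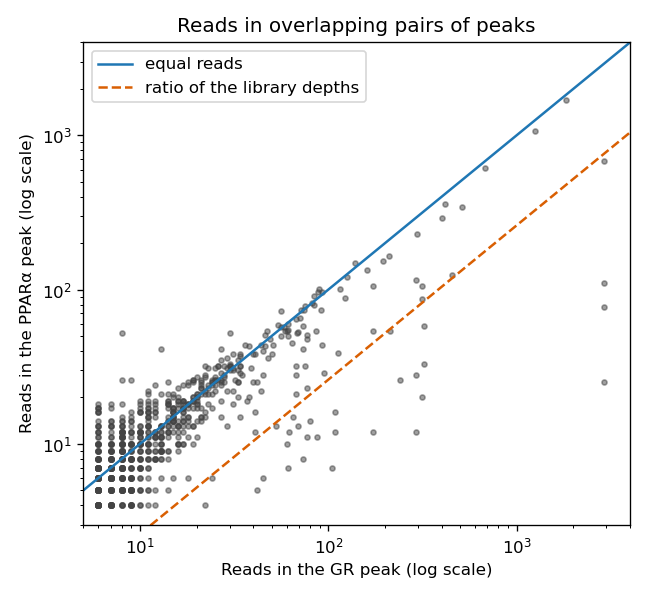
Reads after duplicate removal in the GR peak (x axis) and in the PPARα peak (y axis) of each of the 774 overlapping pairs, both on log scales. The solid line marks equal reads and the dashed line the ratio of the library depths, 0.261. Most pairs lie near the solid line.

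The PPARα list was longer although its library was smaller. It held 1651 peaks with a median of 6 reads (quartiles 4 and 11), and the GR list held 1157 peaks with a median of 9 reads (quartiles 7 and 16). Peaks took up 2.40% of PPARα reads (exact 95% interval 2.38 to 2.42%) and 0.385% of GR reads (0.380 to 0.389%). A single stretch at the start of the chromosome 9 sequence accounted for much of this. From 3000001 to 3038400 the PPARα list had 14 peaks covering 98.9% of the stretch and holding 24475 reads, which was 52.1% of all PPARα reads in peaks. Their folds were 11.3 to 21.4. The GR list had no peak there, and its first peak on chromosome 9 began at 3258742. Without this stretch, 1.16% of the remaining PPARα reads lay in peaks. The GR share was not recomputed in this way. It includes places where the input was also read often, such as a peak on chromosome 17 with 2917 of the 28925 GR reads in peaks. The remaining PPARα peaks include such places too. Of the 886 peaks found in the PPARα list alone, 641 had 4 or 5 reads.

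The peaks were narrow. The median width was 110 bp for GR (quartiles 76 and 141) and 69 bp for PPARα (quartiles 52 and 104). Under 80 bp, or 2 read lengths, lay 28.4% of GR peaks and 58.9% of PPARα peaks. Widths below 200 bp, the smallest library fragment selected according to the protocol, made up 88.9% and 95.3%. The width of a called peak is not a measured fragment length. The fragment length that the peak caller estimated was 42 bp for GR and 38 bp for PPARα, with reads of 40 bp. Shared GR peaks had a median width of 98 bp and GR-only peaks 120.5 bp. Shared PPARα peaks had a median width of 76 bp and PPARα-only peaks 62 bp.

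**Figure D4:**
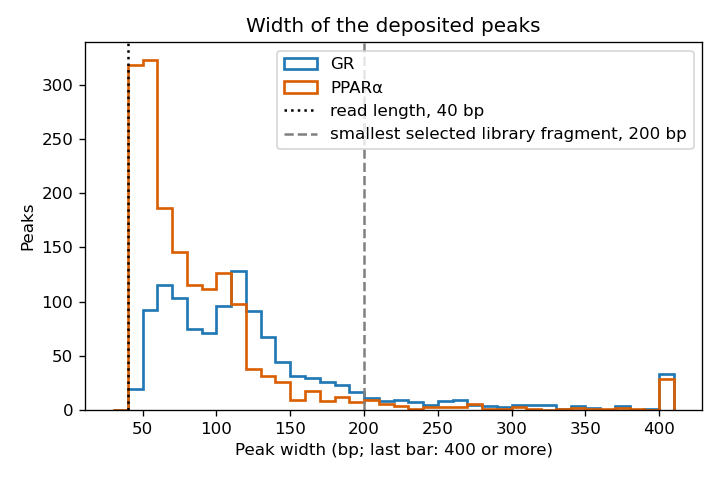
Number of peaks (y axis) by peak width in bp (x axis, bins of 10 bp) in the GR and PPARα lists, with wider peaks gathered in the last bin. The dotted line is the read length of 40 bp and the dashed line the smallest selected library fragment of 200 bp. Medians are 110 bp for GR and 69 bp for PPARα.

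GR and PPARα peaks were found on all autosomes and on X and Y, and their spread over chromosomes was compared over all peaks and over unshared peaks. Chromosome 13 held the most GR peaks, 106 (9.16%), against 95 PPARα peaks (5.75%). Chromosome 3 held the most PPARα peaks, 107 (6.48%), against 83 GR peaks (7.17%). Chromosome Y had 11 GR and 21 PPARα peaks. The chi-square statistic over chromosomes was 25.4, and 81.3% of 100000 reassignments of peaks to the lists gave less (permutation p = 0.19). That test counts shared sites in both lists. Among peaks found in 1 list only, a comparison added after the data were seen, the statistic was 53.6 (permutation p = 7e-05). Chromosome 13 then held 47 of 406 GR-only peaks (11.6%) and 33 of 886 PPARα-only peaks (3.72%). With runs of 8 or more neighbouring peaks left out the statistic fell to 18.4 (permutation p = 0.56), with 15 of 331 and 31 of 852 on chromosome 13. Peaks in a run are not independent, so the p over all unshared peaks does not count independent sites. The share of GR peaks that were shared ranged from 36.4% on chromosome Y, with 4 of 11 peaks, to 87.5% on chromosome 16, with 28 of 32. GR peaks also occurred in groups. On chromosome 18, 11 GR and 11 PPARα peaks lay between 53221908 and 53237433, while on chromosome 11, 10 GR peaks from 68850405 to 68938767 had no PPARα counterpart. Both regions were picked after the peaks were seen.

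**Figure D5:**
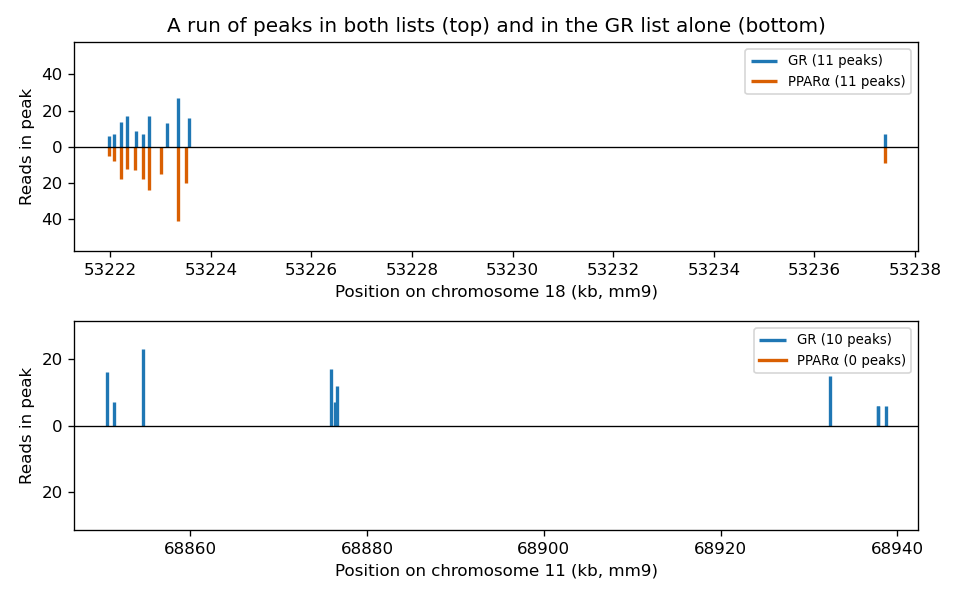
Reads in each peak (y axis, GR upward and PPARα downward) by summit position in kb on mm9 (x axis) for a stretch of chromosome 18 and one of chromosome 11. The stretch of chromosome 18 has 11 peaks in each list, that of chromosome 11 has 10 GR peaks and no PPARα peak.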

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

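The restrictions to whole-read folds, to peaks of at least 80 bp, to peaks outside runs, to summits away from the midpoint and to unshared peaks were chosen after the data were seen. The overlap stayed above chance placement (permutation p = 1e-04) in all 11 alternatives, with 38.3 to 70.4% of GR peaks and 42.4 to 48.3% of PPARα peaks shared. The lowest GR share came from leaving out peaks under 80 bp, which removed 329 GR and 973 PPARα peaks, and the highest from a fold of 20 or more. Shared peaks kept the higher median fold or score in every alternative tried, by 1.52 to 1.83 times in the GR list and 1.75 to 2.33 times in the PPARα list. The median summit distance was 4 bp except at 7 bp without peaks under 80 bp and 6 bp for summits over 5 bp from the midpoint. The chromosome statistic stayed inside the range of reassignments (permutation p = 0.052 to 0.36), with the lowest p for the fold 10 lists, over all peaks. Among unshared peaks it was 53.6 (permutation p = 7e-05), and 18.4 (permutation p = 0.56) without runs of peaks, where no difference was detected. A fold of 20 left 947 GR and 1564 PPARα peaks. The FDR limit of 5% removed 13 GR peaks, and these were among the strongest, with a median score of 1046 against 99.4 for the rest, because 1 peak of input over ChIP sets the FDR where few peaks score higher. All PPARα FDR values are 0. Gene lists, genomic location and motifs were not run under any setting. No paired analysis was possible because each group has 1 library. In the PPARα list, peaks rest on a median of 6 reads and a fold of 10 corresponds to less than 1 read. How depth affects that list was not tested.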

Other observations

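Runs of neighbouring peaks, defined after the data were seen as 8 or more peaks less than 100 kb apart, held 116 GR peaks in 10 runs and 77 PPARα peaks in 7 runs. GR runs lay on chromosome 13, from 23529939 to 23673803 with 19 peaks, from 21802826 to 22121190 with 17 and from 21259936 to 21370703 with 9. Others lay on chromosome 3 from 96042463 to 96305078 with 11 peaks, and on chromosome 6 from 47601045 to 47728267 with 11. In 2 GR runs the PPARα list had no peak at all. These were chromosome 1 from 172964005 to 173032022, with 11 peaks and 171 reads, and chromosome 11 from 68850405 to 68938767, with 10 peaks and 115 reads. The share of GR peaks that overlapped a PPARα peak was 35.3% inside runs and 68.2% outside. For PPARα peaks the shares went the other way, 55.8% inside and 45.9% outside. Neither difference was tested.

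A compact run was common to both lists. On chromosome 18, from 53221908 to 53237431, 11 GR peaks with 140 reads were all shared. The PPARα list had 11 peaks with 183 reads from 53221911 to 53237433, of which 10 were shared. All but the last of the GR peaks ended by 53223658, and the last began at 53237372. Median folds there were 46.6 for GR and 276.2 for PPARα, above the medians of their lists. Some wide peaks with many reads were also common. On chromosome 2, GR peaks from 98502370 to 98503155 and from 98506391 to 98507509 held 1252 and 1833 reads with folds of 4.73 and 4.68. The PPARα peaks there held 1062 and 1695 reads with folds of 17.9 and 17.7. At the genome-wide background the GR folds would be worth 0.798 and 0.790 reads and the PPARα folds 0.714 and 0.705. The input was therefore also read often at these places. On chromosome 17, the GR peak from 39979900 to 39985775 held 2917 reads, and the 4 PPARα peaks that overlapped it held 897 together. The GR fold of 12.5 there would be worth 2.12 reads, so the background was raised there too.

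Of the tests in the next paragraphs, that of the cap on reads and that of input in all GR runs together had their outcomes set before they were computed, and the others, with each GR run taken by itself, were chosen after the result was seen.

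GR and PPARα peaks lay at nearly the same positions. The shared input is argued against as the whole cause, since an input can only remove peaks and the overlap was 3978 times that of shifted lists. One library sequenced under 2 labels would have to account for the chromosome 9 stretch, which held 52.1% of PPARα reads in peaks and no GR peak. This cannot decide the question, because the criterion was set once the stretch was known and GR reads there were not counted. Cross-contamination limited to the shared sites was not tested. Short stretches of DNA near the read length stay open, since in 85.7% of overlapping pairs (663 of 774, exact 95% interval 83.0 to 88.1%) both peaks were narrower than the smallest selected fragment, but the widths of all peaks in both lists alone give 84.7%. Occupancy of the same sites by both receptors, and nonspecific enrichment common to both antibodies, stay open, as no list from another antibody or from untreated cells was analysed here.

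Shared peaks held about as many reads in the PPARα library as in the GR library of 3.83 times the depth. Keeping 1 read per position could cap the reads. Among 74 pairs with at least 25 GR reads that filled under 25% of the available positions, the lower quartile of the ratio was still 0.524. That is above the depth ratio of 0.261, the outcome set as going against a cap. Reads removed at single positions were not counted, so low filling over a whole peak cannot exclude a cap at a few crowded positions. Restricting the comparison to peaks called in both lists adds to the pattern, since 36 of the 176 GR peaks with at least 25 reads had no PPARα peak. With those counted as below the depth ratio, 129 of 176 (73.3%, exact 95% interval 66.1 to 79.7%) still lay above it, and 90 of the 137 that filled under 25% of positions, so for these peaks it is argued against as the whole cause. A cap at crowded positions, selection among GR peaks with fewer reads, and a larger share of PPARα reads at these sites for biological or library reasons stay open.

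The GR list had runs of peaks and the PPARα list had a run at the start of chromosome 9. Even random placement along the chromosomes is argued against as the cause of the GR runs. In 0 of 1000 draws was the largest run as large as that observed at any of 6 gaps from 10 to 500 kb. Peaks lying close together, as on chromosome 18, were counted singly and were not merged. Regional differences in the density of peaks were not tested. For the PPARα run, sequence with many copies is a candidate explanation, since the background implied by reads and folds was at least 22.6 times the genome-wide one, meaning that the input was read often there too. The folds of 11.3 to 21.4 are already over that background. The enrichment itself, and the lack of a GR peak there, stay unexplained. The same explanation is argued against for the GR run on chromosome 18. There 10 of 11 peaks (90.9%, exact 95% interval 58.7 to 99.8%) had whole-read folds, as the genome-wide background gives. The explanation predicts under 25%, and 50% or more was set as going against it. This run had the highest share of the 10 GR runs, and the interval treats neighbouring peaks as independent. All but the last of its peaks lay between 53221908 and 53223658, so they may not be separate sites. In all GR runs together the share was 44.8% (52 of 116), against 69.2% of the GR peaks outside runs. For the other 9 runs the explanation stays open. Of these, 4 runs on chromosomes 3, 11 and 13 had shares of 52.9 to 68.4% with intervals that begin at 26.2 to 43.4%. The runs on chromosomes 6, X and Y had none among 28 peaks, as the explanation predicts, but with intervals that reach above 25%. Their median folds were 10.99, 7.755 and 5.22, against 35.5 in the GR list. On Y, 9 peaks of median width 51 bp held 88 reads. The median fold there was below the 5.92 that a read is worth at the genome-wide background, so the background was raised. For the runs on chromosomes 6, X and Y, sequence with many copies is therefore a candidate explanation, but copy number was not tested.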
